A study of Mus musculus with 6 samples.

How the data were processed

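Gene expression was measured by RNA sequencing in 6 tumours grown from Hep1-6, a mouse hepatoma cell line, after injection under the skin of C57BL/6J mice. Per the labels, 3 tumours came from mice on a normal diet (ND) and 3 from mice on a high cholesterol diet (HCD). Total RNA was isolated with a column kit and paired-end libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. Strand use in counting is not given in the sources used here, so genes that overlap on opposite strands cannot be separated.

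The deposited table holds FPKM values (fragments scaled by gene length and library size) for 34745 mouse Ensembl gene IDs, with 1 column per sample, per the file headers. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.9, HTSeq, edgeR and the build mm10, without saying which step each served. The annotation release used by the authors is not given in the sources used here. Every value column belonged to a labelled sample.

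FPKM values are not counts. The plan made before the data were examined used a count model if counts were present and otherwise limma on log values, and the second was applied. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 13417 in all, on log2(FPKM + 1). The limma fit (limma 3.58.1 in R 4.3.3) had diet as its only term, with a trend of the variance on the mean, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Differences are HCD minus ND on the log2(FPKM + 1) scale, which understates the change of genes with low values. Counts of list members with a higher or lower mean were taken on that scale too. Adjusted p-values of single genes in the report are from this fit.

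In all, 25 gene lists were fixed from textbook knowledge before the data were examined. They covered sterol synthesis and uptake, sterol export and LXR targets, fatty acid synthesis, fatty acid oxidation, hepatocyte identity, leukocyte classes, antigen presentation, interferon responses, inflammatory cytokines, cell cycle, hypoxia and glycolysis, stress responses, stroma, and tissues that a tumour piece can carry along. Lists were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the 25 lists. Camera was given the same variance trend as the gene fit; it was also run without the trend, a choice made after seeing the data. Camera with a correlation estimated for each list, and fry, a rotation test of each list by itself, were alternatives.

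Genes were named by a rule fixed beforehand. It took the 10 called genes with the largest change in each direction. If there were none, it took the 5 with the lowest p in each direction, kept here to genes with at least 1 FPKM in the higher group, no overlap between the groups and no predicted-model name. It also took up to 4 called members of each list, or the 2 with the highest mean where none was called. Hmgcs1, Sqle, Abca1, Abcg1, Ncr1, Gzmb, Prf1 and Ifng were always included. Some genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

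Depth was read from the values. Within a library the FPKM of a gene is a whole number of reads times a step set by gene length and library size. Library sizes of 20351637 to 26228074 fragments accounted for these steps. Gene lengths were searched around the GENCODE M21 exon length so that all 6 values became whole within 0.02 of a read, up to 20000 reads. Whole reads came out for 99.0% of tested genes, against 0.12% of 1617 decoy genes whose values had each been multiplied by a random factor. In simulated data 99.64% of 1681 genes with 100 or more reads were recovered exactly. Genes with fewer reads, among them Trbv29 and Gm37689, were outside that test, and for them the length nearest to M21 was taken. The recovered reads served for depth, for receptor segments and for limma-voom as an alternative. At 2 kb of gene length, 1 FPKM corresponded to 40.7 to 52.5 reads.

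The limma fit was tested on simulated values for the HCD against ND comparison, with 200 of 13417 genes changed, all above a log2 level of 2, and noise drawn independently for each gene. It called 64% of the genes changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 11 false calls. Each size was given to 50 genes. The genes with large changes ease the Benjamini-Hochberg cutoff, so these shares do not hold where few genes change. Simulated noise lacked the shared variation between libraries that the real values show.

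Positions are 1-based, from GENCODE M21 on GRCm38, the assembly that mm10 denotes; 34344 of the 34745 IDs were found there. Alternatives comprised a pseudocount of 0.1, no filter on low values, a 2-fold minimum, the replicate number as a block and leaving out each library in turn. Chosen after seeing the data were median-ratio and upper-quartile scaling, a filter of at least 1 FPKM in 3 or more libraries, limma-voom, leaving out HCD 1 and ND 2, and the muscle list mean as a covariate. Figures were drawn with matplotlib 3.10.9.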

Results

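Tumours grown from Hep1-6 cells under the skin of C57BL/6J mice were profiled by RNA sequencing, 3 from mice on a normal diet (ND) and 3 from mice on a high cholesterol diet (HCD). Library sizes implied by the value steps were 22864685, 26228074 and 20622727 fragments in ND 1 to ND 3, and 20351637, 20425576 and 20918326 fragments in HCD 1 to HCD 3. Between 11495 and 12050 genes reached 1 FPKM in a library. Correlations of log2 values between libraries ranged from 0.9596 to 0.9864. The labels describe tumour tissues from mice of each diet but do not state that each came from a different animal, so p-values measure the spread between these samples.

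Some hepatocyte genes were abundant in all 6 tumours and others were near 0. Of 22 hepatocyte identity genes, 9 lay below the level for testing, with means of at most 0.496 FPKM. Alb, which encodes serum albumin, was at 1375 ± 155 FPKM in ND and 1439 ± 250 FPKM in HCD (SD, n = 3). Rbp4, the plasma carrier of retinol, was at 262 ± 3.81 and 252 ± 25.2 FPKM (SD, n = 3). Of the 13 tested members, 7 had a higher and 6 a lower mean in HCD, and none was called (camera adjusted p = 0.591).

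The comparison of HCD with ND asks which tumour transcripts differ with dietary cholesterol. No gene passed: limma called 0 genes higher and 0 lower at an adjusted p of 0.05 among 13417 tested, and the lowest adjusted p was 0.138. That value belonged to Gm37689, a predicted model on chromosome 4 (6378018 to 6378292) that the naming rule leaves out and that was chosen after its values were seen. It had 13, 20 and 15 recovered reads in ND 1 to ND 3 and 1, 1 and 2 in HCD 1 to HCD 3, with a log2 difference of -1.50 (SE 0.117). At an unadjusted p under 0.05 there were 789 genes, 343 higher and 446 lower in HCD. Limma-voom on the recovered reads also called 0 genes, with 705 at an unadjusted p under 0.05. The groups did not overlap in 12.1% of tested genes, where chance gives 10%. The 95% interval of the log2 difference lay within 1 on either side of no change for 12533 genes, and its median half-width was 0.233.

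The genes with the lowest p that the naming rule takes did not pass either. Trbv29, a variable segment of the T cell receptor beta locus (chromosome 6, 41271394 to 41271881), was listed at 0, 0.54 and 0.137 FPKM in ND 1 to ND 3 and at 2.37, 2.08 and 3.12 FPKM in HCD 1 to HCD 3. Its log2 difference was 1.54 (SE 0.193, adjusted p = 0.700). Trbj1-5, a joining segment of the same locus, differed by 1.48 (SE 0.193, adjusted p = 0.700). Them6, Cln6 and Gpcpd1 had differences of 0.44, 0.31 and 0.40 (adjusted p = 0.794 each). In the other direction, Mnt, a MAX-binding transcriptional repressor (chromosome 11, 74830920 to 74845725), was at 8.88 ± 1.01 FPKM in ND and 5.60 ± 0.405 FPKM in HCD (SD, n = 3), with a log2 difference of -0.58. Dcun1d4, Rhebl1, Myo10 and Inafm1 had differences of -0.42, -0.34, -0.38 and -0.34. These 5 genes had an adjusted p of 0.794.

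Genes of cholesterol synthesis and uptake had lower means in HCD in 23 of 24 tested members, with a median log2 difference of -0.17. Camera called the list lower at the preset correlation (adjusted p = 1.37e-04), and adjusted p = 0.702 with an estimated correlation. No member was called over all genes or adjusted over the list alone. Hmgcs1, which encodes a synthase of the mevalonate pathway, was at 79.2 ± 15.7 FPKM in ND and 72.3 ± 12.8 in HCD (SD, n = 3). Its log2 difference was -0.12 (95% interval -0.59 to 0.34, adjusted p = 0.884). Sqle, which encodes squalene epoxidase, differed by -0.21 (adjusted p = 0.810). The mean list difference of -0.17 was -0.05 without HCD 2, -0.11 without ND 1 and -0.27 without ND 2. Without HCD 2, which had the lowest list mean (3.47), camera gave an adjusted p of 0.172 even at the preset correlation.

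Sterol export genes and LXR targets had higher means in HCD in 10 of 14 tested members, but the list was not called (adjusted p = 0.138). Abcg1, a cholesterol exporter, was at 5.24 ± 1.94 FPKM in ND and 9.92 ± 4.99 in HCD (SD, n = 3), with a log2 difference of 0.77 and an adjusted p of 0.794. HCD 2 had the highest value, 15.6 FPKM, and ND 1 the lowest, 3.01 FPKM. The macrophage markers Lyz2 and C1qa were likewise highest in HCD 2 (399 and 210 FPKM) and lowest in ND 1 (83.6 and 58.2 FPKM). Without HCD 1 the list was called higher at the preset correlation (adjusted p = 0.0310). Abca1 differed by 0.38 (adjusted p = 0.794). Apoe was at 691 ± 60.1 FPKM in ND and 594 ± 136 in HCD (SD, n = 3). Fatty acid synthesis genes were divided, with 8 of 17 means higher (adjusted p = 0.216), and Scd1 and Scd2 differed by 0.04 and -0.14. Fatty acid oxidation genes had 11 of 17 means higher (adjusted p = 0.173). Among them Acadl, a mitochondrial acyl-CoA dehydrogenase, was at 46.2 ± 0.712 FPKM in ND and 53.2 ± 1.29 in HCD (SD, n = 3), with an adjusted p of 0.794, and Plin2 differed by -0.03.

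Lymphocyte genes had higher means in HCD. All 19 tested T cell genes had a higher mean, with a median log2 difference of 0.56, and camera called the list at the preset correlation (adjusted p = 9.66e-05), with adjusted p = 0.702 with an estimated correlation. Cd3g, a chain of the T cell receptor complex, was at 4.53 ± 2.51 FPKM in ND and 8.71 ± 3.85 in HCD (SD, n = 3). Tigit, at 43.1 ± 9.90 FPKM in ND and 48.5 ± 10.4 in HCD (SD, n = 3), lay far above Cd3g and differed by 0.17. Whether T cells were its source was not tested. Of the NK cell and cytotoxic genes 16 of 17 had a higher mean (adjusted p = 3.81e-04 at the preset correlation, adjusted p = 0.702 with an estimated correlation). Gzmb, which encodes granzyme B, differed by 0.68 and Prf1, which encodes perforin, by 0.57, with adjusted p of 0.795 and 0.833. Ifng differed by 0.34 and Ccl5 by 0.74. Ncr1, a receptor of NK cells, had a mean of 0.351 FPKM in ND and 0.571 FPKM in HCD. It was among the members below the level for testing, since 17 of the 23 NK cell and cytotoxic genes were tested. NK cells and T cells as sources of the cytotoxic genes were not told apart. All 4 tested B cell genes had a higher mean (adjusted p = 0.0358 at the preset correlation, adjusted p = 0.702 with an estimated correlation). Ighm ranged from 2.19 to 21.2 FPKM within ND and from 3.56 to 38.1 FPKM within HCD, and Cd79a differed by 0.65. No member of these lists was called over all genes or adjusted over the list alone.

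Much of the spread lay inside the diet groups. The T cell list mean was 0.909, 1.83 and 1.95 in ND 1 to ND 3 and 2.06, 2.54 and 1.69 in HCD 1 to HCD 3, on the log2 scale. ND 1 was the lowest and HCD 2 the highest library. Without ND 1 the mean T cell difference was 0.20 in place of 0.53, and without HCD 2 it was 0.31. At the preset correlation the NK cell and cytotoxic list gave an adjusted p of 0.0526 without ND 1 and 0.166 without HCD 2. The B cell list gave 0.124 without ND 1, 0.106 without HCD 1 and 0.174 without HCD 2. The mean NK cell and cytotoxic difference of 0.43 was 0.16 without ND 1 and 0.18 without HCD 2. The mean B cell difference of 0.59 was 0.37 without ND 1, 0.38 without HCD 2 and 0.98 without HCD 3.

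**Figure D1:**
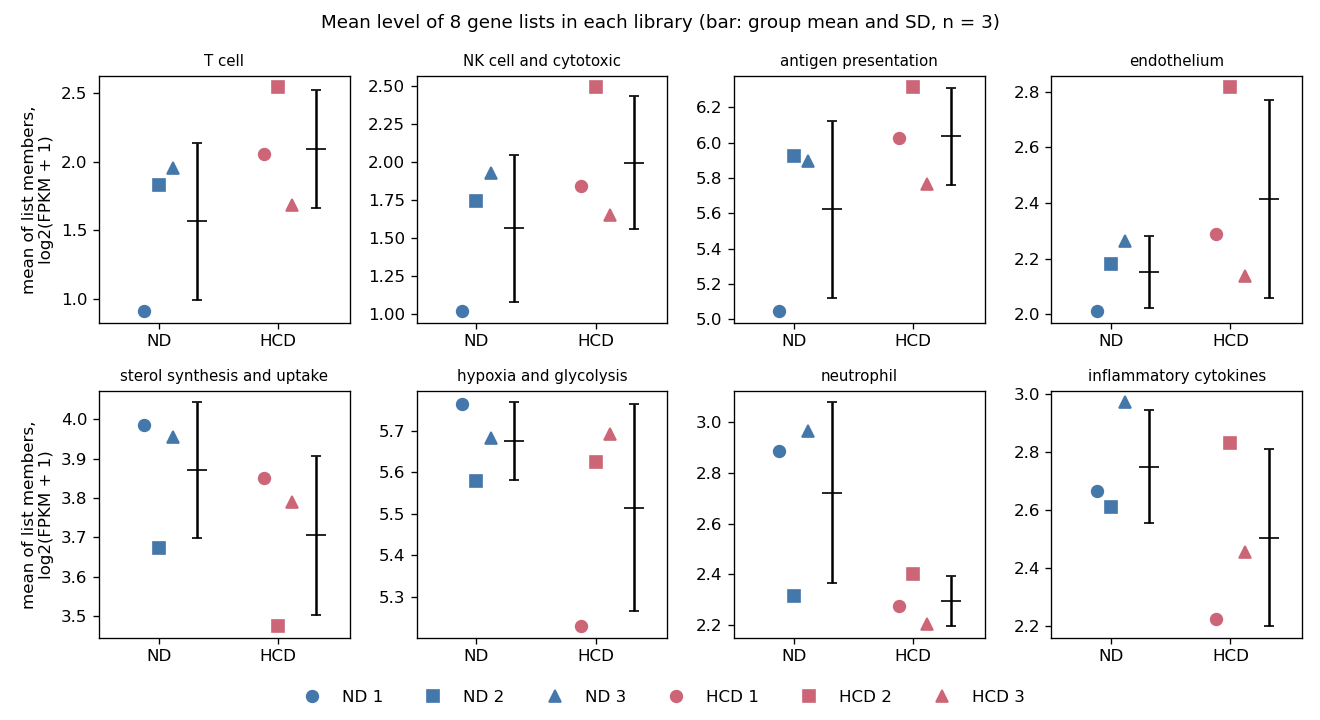
Mean log2(FPKM + 1) of the tested members of 8 gene lists (vertical axes) in each library, by diet (horizontal axes). Symbols are single libraries and the bars give the group mean and SD of 3 libraries; ND 1 lies lowest for T cell genes (0.909) and HCD 2 highest (2.54), and the neutrophil mean of ND 2 (2.31) lies among those of the HCD libraries.

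Antigen presentation genes had higher means in HCD in 17 of 17 tested members (adjusted p = 1.37e-04 at the preset correlation, adjusted p = 0.702 with an estimated correlation). Cd74, the invariant chain of MHC class II, was at 504 ± 218 FPKM in ND and 744 ± 204 in HCD (SD, n = 3), and B2m differed by 0.16. The list mean was 5.04 in ND 1, against 5.93 and 5.90 in ND 2 and ND 3, which lay above HCD 3 (5.77). The mean difference of 0.41 was 0.12 without ND 1 and 0.27 without HCD 2. Interferon gamma response genes had 18 of 18 means higher (adjusted p = 0.0136 at the preset correlation, adjusted p = 0.702 with an estimated correlation), and Gbp2 and Cxcl9 differed by 0.53 and 0.55. Without ND 1 this list turned to the lower side with an adjusted p of 0.993, and without HCD 2 its adjusted p was 0.816. Its mean difference of 0.30 was -0.002 without ND 1, 0.07 without HCD 2 and 0.49 without ND 3. The type I interferon list was not called (adjusted p = 0.216), and Bst2 and Ifi27l2a differed by 0.33 and 0.20. Its mean difference of 0.12 was -0.10 without ND 1 and -0.03 without HCD 2, and it was called higher without ND 2, ND 3 or HCD 1 (adjusted p = 0.0205, 0.0144 and 0.00278 at the preset correlation). Macrophage genes had 18 of 21 means higher without a call (adjusted p = 0.0651), with Lyz2 at 164 ± 74.6 FPKM in ND and 257 ± 137 in HCD (SD, n = 3), and C1qa differing by 0.58. The mean macrophage difference of 0.27 was 0.08 without ND 1 and 0.01 without HCD 2. The list was called higher without ND 2, ND 3, HCD 1 or HCD 3 (adjusted p = 0.0109, 0.0408, 0.00278 and 0.00154 at the preset correlation). Dendritic cell genes had 9 of 9 means higher without a call (adjusted p = 0.110), with Itgax and Irf8 differing by 0.58 and 0.01. The sign of the Irf8 difference turned without ND 1, without HCD 2 and under upper-quartile scaling. The mean dendritic difference of 0.22 was 0.04 without ND 1 and 0.10 without HCD 2, and the list was called higher without ND 2 or HCD 3 (adjusted p = 0.0104 and 0.0108 at the preset correlation).

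Neutrophil genes had lower means in HCD in 9 of 10 tested members, with a median log2 difference of -0.49 (adjusted p = 3.10e-04 at the preset correlation, adjusted p = 0.702 with an estimated correlation). Ngp had the higher mean on the log2 scale, with 0.70 FPKM in ND and 1.1 in HCD. Fpr1 had a log2 difference of -0.03 but a higher FPKM mean in HCD, 3.41 against 2.47 in ND, with 8.02 FPKM in HCD 2. Ly6g, Camp and Ltf lay below the level for testing, with means of 0.41, 0.45 and 0.24 FPKM in ND and 0.44, 0.26 and 0.24 in HCD. Ngp, Fpr1, Ly6g, Camp and Ltf were chosen after their values were seen. S100a9, an abundant calcium-binding protein of neutrophils (chromosome 3, 90692632 to 90695721), was at 61.2, 19.1 and 60.2 FPKM in ND 1 to ND 3 and at 18.0, 20.4 and 19.9 FPKM in HCD 1 to HCD 3 (log2 difference -1.06, adjusted p = 0.794). Without ND 2, S100a9 was called, with a log2 difference of -1.60 and an adjusted p of 0.0334, as the only gene in that fit. S100a8 differed by -0.71. Inflammatory cytokine genes had 14 of 17 means lower (adjusted p = 3.10e-04 at the preset correlation, adjusted p = 0.702 with an estimated correlation), and Nfkbia and Ccl7 differed by -0.26 and -0.30. Without HCD 1 this list gave an adjusted p of 0.0778 at the preset correlation. Its mean difference of -0.25 was -0.11 without HCD 1, -0.13 without ND 3 and -0.41 without HCD 2.

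Hypoxia and glycolysis genes had lower means in HCD in 19 of 20 members, with a median log2 difference of -0.15 (adjusted p = 1.83e-04 at the preset correlation, adjusted p = 0.702 with an estimated correlation). Gapdh and Ldha differed by -0.02 and -0.09. Hk2, chosen after its values were seen, counted as lower at a log2 difference of -0.01, with 22.24 FPKM in ND and 22.75 in HCD. HCD 1 had the lowest list mean (5.23). The mean list difference of -0.16 was -0.02 without HCD 1, where the adjusted p was 0.587, and -0.25 without HCD 3. Cell cycle genes had 21 of 25 means higher (adjusted p = 0.00409 at the preset correlation, adjusted p = 0.702 with an estimated correlation), with Mki67 and Top2a differing by 0.09 and 0.06. Without ND 3 that list gave an adjusted p of 0.588, and without HCD 3 one of 0.216. Its mean difference of 0.09 was 0.03 without ND 3, and 0.15 without ND 2 or HCD 2. Endothelial genes had 15 of 15 means higher (adjusted p = 0.00190 at the preset correlation, adjusted p = 0.702 with an estimated correlation), with Plvap and Esam differing by 0.38 and 0.25. Without HCD 2 that list gave an adjusted p of 0.519, and its mean difference was 0.06 in place of 0.26. Without HCD 3 the mean endothelial difference was 0.40. The stress response list (adjusted p = 0.347), with Calr and Hspa5 differing by 0.04 and -0.13, the immediate early list (adjusted p = 0.518), with Junb and Ier3 differing by -0.33 and -0.63, and the fibroblast list (adjusted p = 0.488), with Dcn and Fn1 differing by -0.11 and -0.30, were not called. At the preset correlation the fibroblast list was called lower without HCD 2 (mean difference -0.24, adjusted p = 4.61e-04) and higher without HCD 3 (mean difference 0.20, adjusted p = 0.0416).

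Skeletal muscle genes varied widely within both groups. Acta1, the skeletal muscle actin, was at 3.02, 275 and 7.95 FPKM in ND 1 to ND 3 and at 448, 43.5 and 3.77 FPKM in HCD 1 to HCD 3. The mean of the muscle list was 4.50 in ND 2 and 4.95 in HCD 1 on the log2 scale, 2.46 in HCD 2 and between 0.708 and 0.961 in the others. The list was not called (adjusted p = 0.173), and Eno3 differed by 0.15. Car3, abundant in adipocytes and slow muscle, was at 12.4 FPKM in ND 2 and 47.6 FPKM in HCD 1, and Pnpla2 differed by 0.05; the adipocyte list was not called (adjusted p = 0.216). The skin epithelium list (adjusted p = 0.138), with Dsp and Sfn differing by -0.11 and 0.33, and the red blood cell list (adjusted p = 0.278), with Hbb-bs and Hba-a1 differing by 0.23 and 0.59, were not called. At the preset correlation muscle genes were called higher without ND 2 or HCD 3 (adjusted p = 5.93e-05 and 0.00163), adipocyte genes without HCD 3 (0.0218) and skin genes without HCD 1 (0.00639). Red blood cell genes were called higher without ND 2 or HCD 1 (0.0410 and 0.0358). The mean muscle difference of 0.67 was -0.44 without HCD 1 and -0.004 without ND 1. Without HCD 3 the skin difference of 0.32 was 0.04 and the red blood cell difference of 0.42 was 0.05. Hba-a1 shares reads with a near-identical copy and is uncertain.

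**Figure D2:**
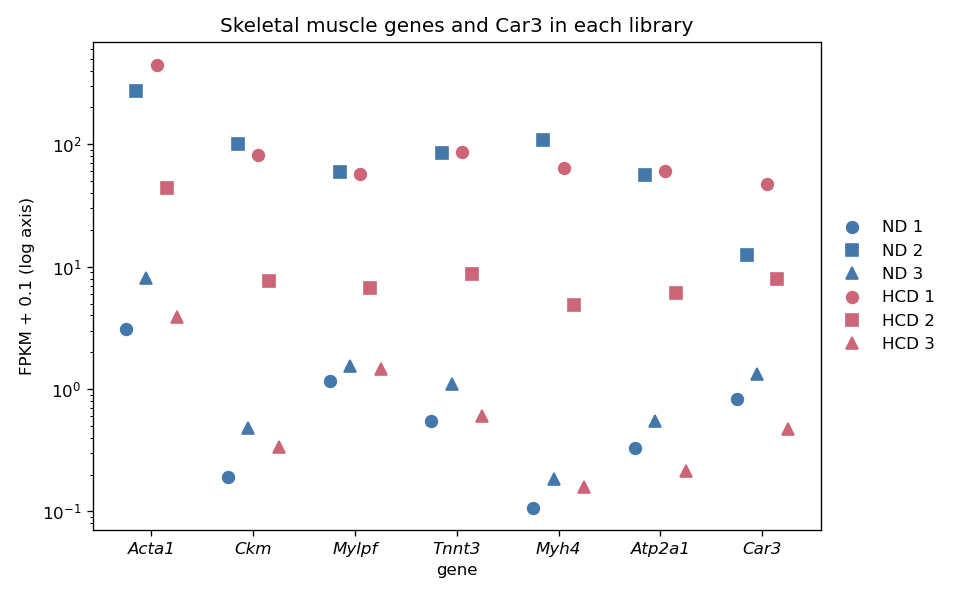
FPKM plus 0.1 on a log axis (vertical) of 6 skeletal muscle genes and Car3 (horizontal) in each library; symbols are single libraries. ND 2 and HCD 1 lie highest for each gene, with Acta1 at 275 and 448 FPKM, and HCD 2 (43.5 FPKM for Acta1) lies between them and the other libraries.

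In all, camera called 11 of 25 lists at the preset correlation, 7 higher and 4 lower in HCD, and 0 with an estimated correlation. Estimated correlations within the 11 lists ranged up to 0.937, and fry called 0 lists (lowest adjusted p = 0.744 for its directional and 0.732 for its mixed test). Of the 11 lists, 3 kept their preset call with each library left out in turn: T cell, neutrophil and antigen presentation. Without ND 1, however, the mean log2 difference was 0.20 in place of 0.53 for T cell genes and 0.12 in place of 0.41 for antigen presentation. A single list mean compared by exact permutation of 3 against 3 libraries cannot give a two-sided p below 0.1.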

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

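Scaling, the filter of 1 FPKM, limma-voom, the omission of HCD 1 and ND 2 together, the muscle covariate and camera without a variance trend were chosen after seeing the data. The count of genes called was 0 in each direction in every setting run, except 1 gene lower (S100a9) without ND 2; leaving out each library gave 0 to 0 genes higher and 0 to 1 lower. The count of lists called was 11, and 0 with an estimated correlation, 0 with directional fry and 0 with mixed fry. Those tests take the correlation between members into account. Leaving out each library gave 7 to 16 lists, the lowest without HCD 2. Without ND 1 the interferon gamma list turned to the lower side (adjusted p = 0.993, against 3.56e-05 without ND 3). ND 1 had the lowest mean of this list among all libraries (4.03), and ND 3 the highest within ND (5.01). Why ND 1 was low was not tested. Of the 14 lists not called, 9 were called at the preset correlation with some library left out, down to an adjusted p of 5.93e-05 for muscle without ND 2; the calls of the fibroblast list went in opposite directions. Scaling, filters and pseudocount gave 10 to 12 lists, limma-voom 13, and omission of HCD 1 and ND 2 gave 16. Of 978 values of named genes in other settings, 945 kept their direction and remained uncalled, 32 changed sign without a call and 1 was called.

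Pairing by equal replicate numbers was not seen. Correlations of their deviations from the group means were -0.19, 0.14 and 0.059, and 0 of 6 libraries lay closest to their own number. So few libraries cannot exclude a shared day or cage, on which the labels are silent. With the replicate number as a block, 0 genes were called in each direction and 15 lists were called at the preset correlation. Alternatives that need deposited counts were not run: the count-model normalizations, the filter on CPM, the planned count tools and list tests under those normalizations. Depth limits genes near 0.5 FPKM, where, at a given gene length, a read more or less moves the log2 value most among tested genes. The step of a read in FPKM depends on gene length and library size and is larger in short genes.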

Other observations

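The most abundant transcripts were mitochondrial, led by mt-Co1 at 9645 ± 380 FPKM in ND and 9538 ± 612 in HCD (SD, n = 3); Gm10925 and Gm28661, listed near them, are uncertain because reads can be shared with mitochondrial genes. Immunoglobulin variable segments held 274, 2169 and 1012 recovered reads in ND 1 to ND 3 and 2823, 3157 and 506 in HCD 1 to HCD 3. Krt14, a keratin of basal epidermis, was at 7.48 FPKM in HCD 3 and between 0.0559 and 0.802 FPKM in the other 5 libraries. These genes were chosen after their values were seen.

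Apart from the count of genes called over other splits of the libraries, the tests in this part were chosen after the results were seen. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In 10 of them, the real one included, the number of genes called was as large as the real 0, the highest other being 0. A real count of 0 fixed that outcome, so it decides nothing. At an unadjusted p under 0.05 the real split gave 789 genes and the highest other 1321, with 4 splits as large, the real one included. That highest split set ND 2, HCD 1 and HCD 2 against ND 1, ND 3 and HCD 3, as did the first principal component (46.3% of the variance). For lists called at the preset correlation the real split gave 11 and the highest other 16. There were 6 splits as large, the real one included, and no split gave fewer than 4.

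Skeletal muscle genes were high in HCD 1 and ND 2. A scaling difference is argued against, since median-ratio scaling removed 0.59% of the gap. Diet as the whole cause is argued against too, since the smaller range within a diet was 5.65 times the difference of the diet means. The pattern was named after its values were seen and has a high library in each diet, so this ratio largely restates it. Muscle tissue in the sampled piece may account for the pattern: of 29 tested genes of a second muscle list, 89.7% lay at least 5 times above the median of HCD 3, ND 1 and ND 3 in both libraries. Those genes were kept by a mean that HCD 1 and ND 2 raise, so the share partly repeats the pattern. It cannot tell muscle tissue in the piece from another source of muscle RNA. The labels place the tumours under the skin but do not describe how they were cut out.

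T cell genes had higher means in HCD. A single library could carry much of this: without ND 1, 38.2% of the mean difference was left. With the muscle list mean as a covariate 88% was left, but the interval ran from -179% to 355%, so muscle tissue cannot be told apart from other sources with 6 libraries. An effect of diet stays open and was not shown by these tests.

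Trbv29 made up 15.0%, 14.7% and 33.8% of the reads of all Trbv segments in HCD 1 to HCD 3 and 0%, 5.05% and 0.971% in ND 1 to ND 3. More T cell RNA alone would leave this share unchanged; pooled reads, 55 of 283 in HCD and 6 of 220 in ND, gave p = 1.76e-09 by Fisher's exact test. That p covers counting error only, since reads of the same library or T cell clone are not independent, and it compares these libraries, not the diets. The exact 95% intervals of HCD 1 (9.01% to 23.0%) and HCD 2 (8.47% to 23.1%) each overlap those of ND 1 (0% to 18.5%) and ND 2 (1.66% to 11.4%). That of HCD 3 (22.8% to 46.3%) lies above those of all 3 ND libraries, and that of ND 3 (0.0246% to 5.29%) below those of all 3 HCD libraries. As some intervals overlap and the segment was picked among 13417 genes for its difference, the explanation stays open. A shared expansion of T cells using this segment is a hypothesis that may be worth a look at receptor sequences, which were not analysed here.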
